A study of Rattus norvegicus with 2 samples.

How the data were processed

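Liver left in place after partial hepatectomy (PH), the surgical removal of part of the liver, was profiled in the rat. The groups were 1/3PH and 2/3PH, named for the fraction removed, and tissue was taken at 24 h in both. Per the series' design text, the RNA of 3 rats was pooled in each group, and each pool was measured on 1 array, so the 6 rats gave 2 measurements. Per the labels' protocols, cRNA was made with an Affymetrix 3' IVT Express kit, carried biotin, and was hybridised in an Oven 645, washed on a Fluidics Station 450 and read on a Scanner 3000 with Command Console 3.1. The signal was computed with MAS 5.0 in GeneSpring 11.0, per the labels' protocols. MAS 5.0 combines the probe pairs of each probe set into 1 signal and scales each array by a single factor.

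The deposited values are log2 MAS 5.0 signals of 31099 probe sets per array. The log2 base was checked on the values. Read as powers of 2, the mean signal without the top and bottom 2% of probe sets was 500.3 on the 1/3PH array and 500.2 on the 2/3PH array. Natural and base 10 logs gave no such shared value. The scaling target and the detection calls are not given in the sources used here, so a floor on signal took the place of calls. Because this scaling sets both arrays to the same mean, a change in the total RNA per cell cannot be read from the deposited values.

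Probe sets were named from the platform's annotation, with symbols updated through Entrez identifiers to the rat RefSeq table of assembly GRCr8. Of the 31042 probe sets that were not controls, 20826 had 1 symbol, 436 had several and were not named, and 9780 were not listed in that annotation. The 57 control probe sets were kept out of gene counts. No genome coordinates are given, since the annotation used here pairs probe sets with genes and not with positions.

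Each of 14217 genes was represented by its probe set with the highest mean log2 signal. The floor was the median of the mean log2 signal over all probe sets that were not controls, 6.48, a signal of 89.2, and 9514 genes reached it. The quantity compared was the log2 ratio, 2/3PH minus 1/3PH, on the deposited scale. A gene was called higher or lower at a ratio of 2-fold or more. Where the dimmer array lay under the floor signal, the fold is given as "at least", computed with the floor signal in its place. With 1 array per group there is no replicate error, so no test was made and no p-value is given. The number of arrays limits the precision.

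A total of 34 gene lists with 993 entries was written before the data were examined. They cover cell cycle, growth control, liver metabolism, secretion, stress, interferon, clock, zonation and markers of other cell types. Of these entries, 27 were matched through a synonym and 111 were not matched to a named probe set. The median log2 ratio of each list's members above the floor was placed among 10000 random lists of the same size, matched in 20 bins of mean signal. A list below the 2.5 or above the 97.5 percentile is described as standing apart. These percentiles describe the 2 arrays and carry no animal-to-animal error. A list gene present in several lists counts in each of them, and 25 genes above the floor did so.

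Named genes followed a rule also fixed before the data were examined. They are the 12 highest and 12 lowest log2 ratios among genes above the floor with a proper symbol, up to 4 members of each list with the largest absolute ratio, and a set of cell cycle, growth factor and liver genes given whatever their value. The error within the arrays was taken from 2067 genes with several probe sets above the floor.

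The procedure was tested on simulated data for 9504 genes with noise of the size seen between probe sets of 1 gene. Of the genes given a log2 ratio of 2, 99 of 99 passed the 2-fold limit, and 96 of 100 did so at a log2 ratio of 1.5. Of 9305 unchanged genes, 12 passed. Of 200 unchanged lists, 5 stood apart, and 100 of 100 lists shifted by 0.5 did so. The simulation holds no variation between animals. It gave all genes independent noise of the same SD, 0.31 for a probe set's ratio. On the arrays that SD was 0.37 for pairs with a dimmer second probe set and 0.24 for pairs with a brighter one. The simulated lists therefore do not cover genes that vary together. On the arrays the log2 ratios of all genes above the floor had an SD of 0.66, so a shift of 0.5 was easier to find in the simulation. Its noise came from probe sets of these same arrays, so the 12 calls leave out error shared by the probe sets of an array.

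Alternatives set before the data were examined were median centring, quantile normalization, removal of a loess trend, no floor, a floor at the 75th percentile, 64 units added before the log, the mean over probe sets, removal of probe sets with the suffixes _s_at, _x_at and _a_at, limits of 1.5-fold and 3-fold, and unmatched random lists. Scaling to the hybridisation controls and scaling to the poly-A controls were added after the data were seen. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots used matplotlib 3.10.9.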

Results

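The 2 arrays measured liver RNA at 24 h after removal of a smaller or a larger part of the rat liver, each from a pool of 3 rats. The comparison addressed which transcripts differ between 2/3PH, which the series' design text describes as followed by strong DNA replication, and 1/3PH, described there as followed by little. Replication itself was not measured by these arrays. The median log2 signal was 6.48 on the 1/3PH array and 6.53 on the 2/3PH array. Across all probe sets, which are not independent replicates, Pearson's r between the arrays was 0.918. There was 1 array per group, so no difference below has a replicate check. The words "higher" and "lower" refer to the 2/3PH array relative to the 1/3PH array. The data held no array of unoperated or sham-operated liver and no other time. A gene lower after 2/3PH may therefore have been raised after 1/3PH, and a delayed response cannot be told from a smaller one.

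Genes of cell division were far higher after 2/3PH, and cholesterol synthesis genes were lower. Lists of lipogenesis, drug metabolism, bile acid transport and the interferon response had medians below those of random lists, with members on both sides of 0. Of 9514 genes above the floor, 582 (6.12%) were at least 2-fold higher and 350 (3.68%) at least 2-fold lower. The difference was more lopsided at larger sizes, with 137 genes at least 4-fold higher and 32 at least 4-fold lower. The 125 genes of the DNA replication, G1/S, mitosis and S-phase lists made up 1.31% of the genes above the floor. They supplied 109 of the 582 genes that were 2-fold higher, 67 of the 137 that were 4-fold higher and 15 of the 20 that were 8-fold higher.

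**Figure D1:**
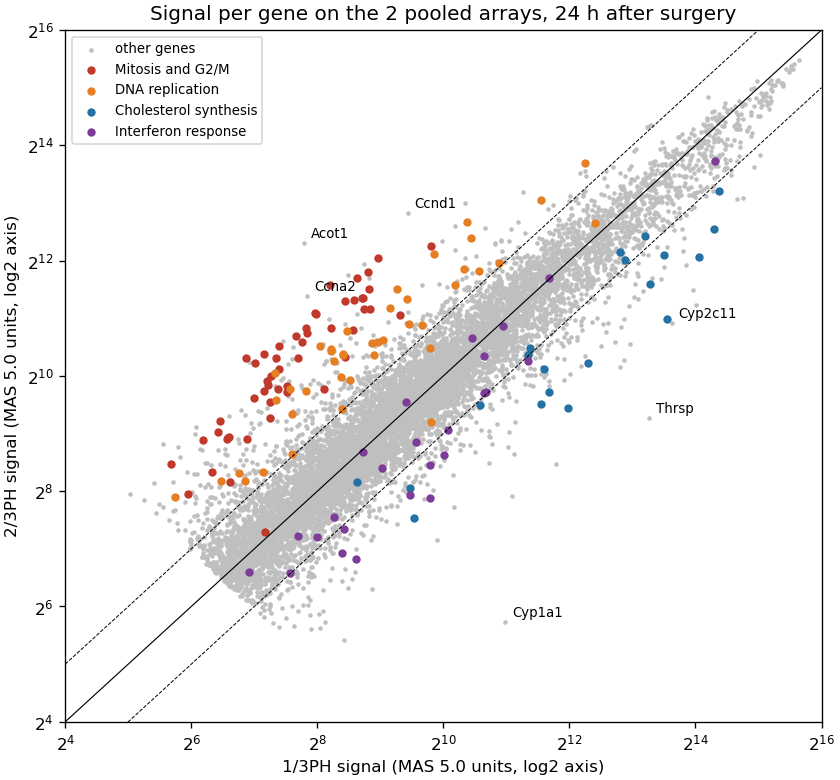
MAS 5.0 signal of each gene above the floor on the 1/3PH array (x axis) and the 2/3PH array (y axis), both on log2 axes, with 1 point per gene. The solid line marks equal signal and the dashed lines 2-fold differences; mitosis and DNA replication genes lie above the upper dashed line in most cases, and cholesterol synthesis genes lie below the line of equal signal.

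The gene with the highest ratio was Acot1, an acyl-CoA thioesterase, with a signal of 222.0 after 1/3PH and 5070 after 2/3PH, a log2 ratio of 4.51. Its near-identical relatives could share its probes, and Acot2 was 2.78-fold higher. The next were Ccna2 (cyclin A2) at 3.55, the mitotic phosphatase Cdkn3 at 3.45, Ccnd1 (cyclin D1) at 3.39, the mitotic kinase Pbk at 3.37 and Shcbp1 at 3.33. Kif18b, a kinesin, stood at 3.28, Tubb6 at 3.26, Aurkb at 3.24, Ttk at 3.21, Mybl1 at 3.20 and Cdc20 at 3.14. For Kif18b the 1/3PH signal was under the floor, and the difference was at least 5.08-fold.

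The lowest ratio was that of Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor. Its signal was 2026 after 1/3PH and 52.8, under the floor, after 2/3PH, at least 22.7-fold lower. Thrsp, a regulator of lipogenesis, had signals of 9851 and 614, Gstp3 was 9.98-fold lower and Sez6 9.01-fold lower. Nfe2, an erythroid transcription factor, was at least 3.86-fold lower and Stac3 at least 5.25-fold lower. Sult1c3, a sulfotransferase, was 6.89-fold lower, the mitochondrial carbonic anhydrase Car5a 6.72-fold and the male-specific Cyp2c11 6.54-fold. Acss2, which makes acetyl-CoA from acetate, was 6.20-fold lower, Hsd17b2 5.98-fold and Insig1 5.94-fold. Cyp2c11 and Gstp3 belong to families with similar sequences.

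**Figure D2:**
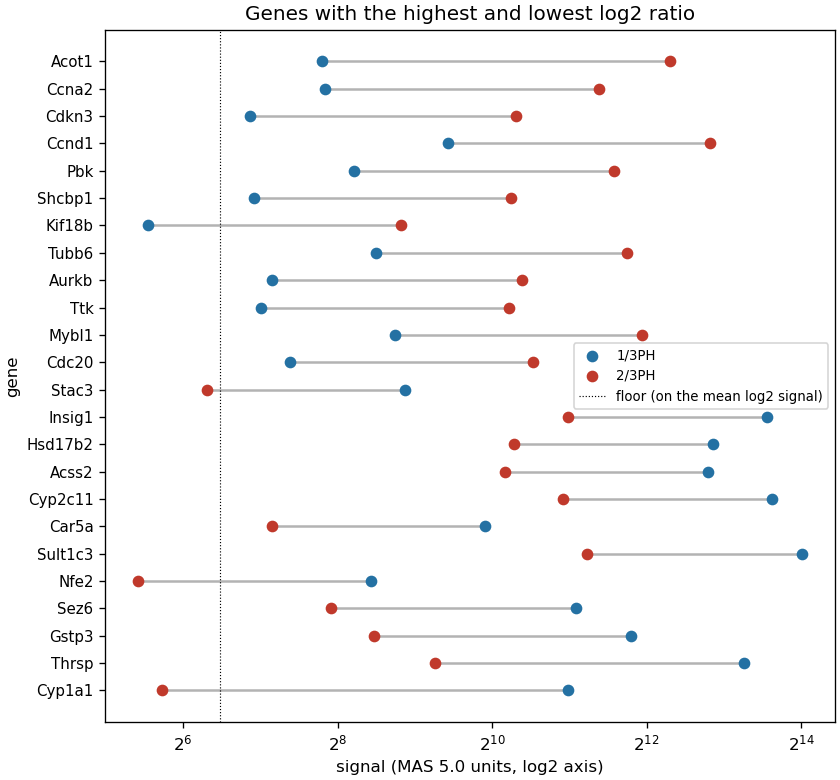
MAS 5.0 signal (x axis, log2) of the 12 genes with the highest and the 12 with the lowest log2 ratio, in blue for 1/3PH and red for 2/3PH, 1 array each. The dotted line marks the floor that was applied to the mean log2 signal of both arrays; Cyp1a1, Nfe2 and Stac3 lie left of it after 2/3PH and Kif18b after 1/3PH.

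Genes of DNA replication were higher nearly throughout. Of 42 measured members, 39 were at least 2-fold higher and none was 2-fold lower. Their median log2 ratio of 1.66 lay above all 10000 random lists. The largest were the replication licensing inhibitor Gmnn, 6.66-fold higher, Mcm3 5.56-fold, the licensing factor Cdt1 4.94-fold and Mcm6 4.87-fold. Mcm2 was 3.02-fold higher, Mcm5 3.09-fold, the polymerase clamp Pcna 2.71-fold and the thymidine kinase Tk1 4.78-fold. Rrm2 had no probe set under that single symbol.

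Mitosis and G2/M genes had the highest median of the 34 lists. Of 51 members, 50 were at least 2-fold higher, with a median log2 ratio of 2.63, or 6.20-fold, above all 10000 random lists. Besides Cdkn3 and Pbk, Aurkb was 9.46-fold and Ttk 9.26-fold higher. Cdk1 was 8.38-fold higher, Ccnb1 8.08-fold, the proliferation marker Mki67 8.47-fold, Top2a 7.96-fold and the transcription factor Foxm1 at least 3.60-fold.

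G1/S regulators were split between large and small differences. Of 17 members, 9 were at least 2-fold higher and none 2-fold lower, with a median of 1.15, or 1.82 over the 9 left by the 75th percentile floor, above all 10000 random lists. Ccna2 was 11.7-fold higher, Ccnd1 10.5-fold, Ccne1 6.90-fold and Ccne2 5.14-fold, and Myc 1.59-fold. Genes of S-phase chromatin and tubulin followed, with 11 of 15 at least 2-fold higher and a median of 1.14, above all 10000 random lists. Tubb6 was 9.57-fold higher, Uhrf1, which maintains DNA methylation, 8.80-fold, Stmn1 5.37-fold and the histone chaperone Asf1b 3.97-fold.

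Ribosome biogenesis genes were higher by smaller amounts. All 42 were higher and 22 were at least 2-fold higher, with a median of 1.02, above all 10000 random lists. Rrp1b was 3.41-fold higher, Ctps1, which makes CTP, 3.24-fold, and the nucleolar proteins Nop58 and Nop56 were 3.24-fold and 2.94-fold higher. Of 14 p53 targets, 6 were at least 2-fold higher and 1 lower, with a median of 0.82, above all 10000 random lists. Cdkn1a (p21) was 4.49-fold higher, Aen 3.24-fold and Phlda3 2.72-fold, whereas Sesn1 was 2.52-fold lower. Cell cycle inhibitors as a list did not stand apart, at a median of -0.21 and the 7.22 percentile, and that median turned positive under both spike-in scalings. In it, Cdkn1a, Cdkn2c (2.56-fold), Cdkn2d (2.16-fold) and Wee1 (2.15-fold) were the higher members at 2-fold, and 1 of 13 was 2-fold lower.

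Cholesterol synthesis genes were lower throughout, and lipogenesis genes were divided. All 20 cholesterol synthesis genes had ratios below 0 and 14 were at least 2-fold lower, with a median of -1.45, below all 10000 random lists. Insig1 was 5.94-fold lower, lanosterol synthase Lss 5.81-fold, squalene synthase Fdft1 4.23-fold and Acat2 4.08-fold. Of 23 lipogenesis genes, 15 had ratios below 0 and 8 above, and 7 were at least 2-fold lower and none higher. Their median was -0.53 at the 0.010 percentile, or -0.29 with hybridisation control scaling and -0.09 with poly-A scaling. Beside Thrsp and Acss2, Acly was 3.33-fold lower and the desaturase Fads1 3.24-fold. Fatty acid oxidation and PPAR-alpha targets did not stand apart, with a median of -0.03 at the 66.8 percentile that turned positive under loess and both spike-in scalings. Of 33 members, 4 were 2-fold higher, among them Acot1 and Acot2, and 2 lower, Ehhadh by 3.59-fold and the fatty acid carrier Cd36 by 2.89-fold.

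Lists of amino acid and glucose metabolism had lower medians. Of 41 genes of amino acid catabolism and the urea cycle, 11 were at least 2-fold lower and none higher, with a median of -0.62, below all 10000 random lists. Kmo, of the kynurenine pathway, was 3.07-fold lower, proline dehydrogenase Prodh 2.88-fold, Gstz1 2.47-fold and Uroc1 2.42-fold. Gluconeogenesis and glycogen genes had a median of -0.35 at the 0.290 percentile, with 2 of 22 lower and 1 higher at 2-fold. That call was lost under quantile normalization, at the 4.61 percentile, and under loess, at 2.53, and the median turned positive under poly-A scaling. Ppp1r3b, a glycogen-targeting subunit of protein phosphatase 1, was 5.30-fold lower and Sds, serine dehydratase, at least 2.60-fold lower. Got1 was 2.02-fold higher and the glucose-6-phosphate transporter Slc37a4 1.84-fold lower.

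Most drug metabolism and bile acid genes were lower, 43 of 48 and 24 of 26. Of 48 cytochrome P450 and phase II genes, 10 were at least 2-fold lower and 1 higher, with a median of -0.59, below all 10000 random lists. Cyp1a1, Sult1c3 and Cyp2c11 led it, and Aox1 was 3.94-fold lower. Of 26 bile acid genes, 8 were at least 2-fold lower and none higher, with a median of -0.76, below all 10000 random lists. Slc10a1, the bile acid uptake carrier, was 5.51-fold lower, Cyp27a1 3.15-fold, Akr1d1 2.69-fold and the export pump Abcc2 2.56-fold. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 2.10-fold lower.

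Hepatocyte lists of sex and zonation had lower medians. The sex-dependent list had a median of -0.77 at the 0.100 percentile, with 2 of 8 at least 2-fold lower, Cyp2c11 and Cyp3a2 (2.10-fold). Cyp2c12 was 1.91-fold and Cyp2a2 1.76-fold lower. The list also holds Y- or X-linked genes and was not split by sex, so its median has no direction toward males or females. Pericentral markers had a median of -0.65 at the 0.110 percentile, with 4 of 11 at least 2-fold lower. Cyp1a2 was 2.98-fold lower, Cyp27a1 and Cyp7a1 as above, whereas Axin2, a Wnt target, was at least 2.69-fold higher. Periportal markers had a median of -0.41 at the 1.02 percentile, with 3 of 17 at least 2-fold lower. That call was lost under quantile normalization (percentile 3.24) and with the 75th percentile floor (4.34), and the median turned positive under poly-A scaling. Sds and Uroc1 were lower as above, Otc was 2.21-fold lower and Asl 1.85-fold higher.

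Most plasma protein genes were lower by less than 2-fold. Plasma proteins of hepatocytes had 40 of 41 members lower and 2 at least 2-fold lower, with a median of -0.36 at the 0.495 percentile that was -0.20 under loess and turned positive under poly-A scaling. Mug1 was 2.34-fold lower, the corticosteroid carrier Serpina6 2.33-fold, C8b 1.86-fold and Mbl1 1.85-fold. Alb, albumin, had a log2 ratio of -0.23, positive under both spike-in scalings, and the fetal protein Afp one of 0.55. Acute phase proteins did not stand apart, at a median of -0.23 and the 11.4 percentile, and the median turned positive under both spike-in scalings. Against random lists not matched on signal it lay at the 1.08 percentile, and its median was -0.03 under quantile normalization and -0.04 under loess. In that list of 26, only Lbp was 2-fold lower, by 2.03-fold, Crp was 1.75-fold lower, Il1rn 1.72-fold higher and Cebpd 1.66-fold higher. Binding proteins of IGF had a median of -0.22 at the 14.5 percentile, which turned positive under both spike-in scalings. Igfbp3 was 3.00-fold lower, its partner Igfals 2.70-fold lower, Igfbp2 1.92-fold higher, Igfbp4 1.20-fold lower and Igfbp1 1.18-fold higher, with 2 of 7 past 2-fold.

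Most interferon response genes were lower, 22 of 25, and 11 of 14 clock genes were, with 3 higher. Of 25 interferon response genes, 9 were at least 2-fold lower and none 2-fold higher, with a median of -0.79, below all 10000 random lists. On the same arrays all 18 macrophage and Kupffer cell markers were lower, with a median of -0.50, as were all 6 neutrophil and erythroid markers, with a median of -0.98. The antiviral genes Mx2, Mx1, Rsad2 and Oas1a were 3.76-fold, 3.45-fold, 2.91-fold and 2.77-fold lower. Of the clock genes, 4 were at least 2-fold lower and none 2-fold higher, with a median of -0.80, below all 10000 random lists. With the 75th percentile floor, which left 7 of them, the median was -0.46 at the 0.870 percentile. Per1 was at least 2.69-fold lower, Nr1d1 at least 3.04-fold, Per3 2.32-fold and Dbp 2.30-fold.

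Growth factor genes showed few large differences. Their median of -0.27 lay at the 0.745 percentile, with 1 of 25 higher and 1 lower at 2-fold. The call was lost under loess (percentile 2.56), without a floor (45.0) and with the 75th percentile floor (2.66), and the median turned positive without a floor and under poly-A scaling. Wnt2 was at least 2.21-fold higher, Inhbc 1.87-fold lower and Fgfr4 1.85-fold lower. Egfr was 2.21-fold lower by its brightest probe set, but its probe sets ranged from -1.14 to 0.36. Hgf stood at -0.33, positive under poly-A scaling, and Met, its receptor, was below the floor, at signals of 20.5 and 54.3.

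Stress lists did not stand apart on the deposited scale. Immediate early genes had a median of 0.26 at the 91.4 percentile, and 99.9 without a floor and 98.5 with the higher floor, with 4 of 16 at least 2-fold higher and 1 lower. Egr1 was 2.80-fold, Ccn1 2.36-fold and Fos 2.11-fold higher, and the phosphatase Dusp1 2.34-fold lower. Heat shock and oxidative stress genes lay at 0.25 and the 97.2 percentile, past the limit under quantile, added units and loess (99.2) but at 78.9 with the mean of probe sets and 92.2 among unmatched random lists, with 3 of 17 at least 2-fold higher. Srxn1 and Gpx2 were each 2.38-fold higher, Hspa1a 2.18-fold higher and Sqstm1 1.66-fold lower. Hypoxia and glycolysis genes lay at 0.26 and the 97.3 percentile, and between 98.2 and 99.6 in 6 of the alternatives but at 92.6 among unmatched random lists, with 1 of 15 at least 2-fold higher. Adm was at least 1.89-fold and Eno1 1.83-fold higher, Ndrg1 1.73-fold and Bnip3 1.55-fold lower. In the ER stress list, at a median of -0.09 and the 41.0 percentile, which turned positive under loess and both spike-in scalings, 1 of 29 passed 2-fold. Sel1l was 2.48-fold lower, Herpud1 1.80-fold lower, Trib3 1.70-fold higher and Ero1b 1.44-fold lower.

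Macrophage, endothelial and stellate lists had lower medians, and members of the last pair lay on both sides of 0. All 18 macrophage and Kupffer cell markers were lower, with a median of -0.50 at the 0.010 percentile, or -0.05 with poly-A scaling, and Lyz2 was the 1 member past 2-fold, at 2.44-fold. Csf1r was 1.77-fold, Ptprc 1.74-fold and Adgre1 1.73-fold lower. Endothelial markers had a median of -0.38 at the 0.280 percentile, which turned positive under poly-A scaling. In that list of 17, 13 had ratios below 0 and 4 above, and Kdr was 2.11-fold lower, Mrc1 1.68-fold, Vwf 1.61-fold and Stab1 1.61-fold. Stellate cell and matrix markers had a median of -0.27 at the 0.290 percentile, which was -0.41 with the 75th percentile floor and turned positive under poly-A scaling, with 18 of 28 below 0, 10 above and 4 at least 2-fold lower. The last were Lum (3.51-fold), Lrat (2.46-fold), Mmp2 (2.09-fold) and Col1a1 (2.05-fold).

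Neutrophil and erythroid markers were lower, with a median of -0.98 over 6 genes, below all 10000 random lists. Hba-a3 was 2.66-fold lower, S100a9 2.52-fold, Hbb 1.99-fold and Alas2 1.96-fold, and globin probes may share related transcripts. Cholangiocyte and progenitor markers did not stand apart, with a median of 0.23 at the 90.3 percentile. Krt18 was 2.09-fold higher, as the 1 of 11 past 2-fold, Krt8 1.62-fold higher, Spp1 1.57-fold lower and Onecut1 1.47-fold lower. The 5 lymphocyte markers had a median of -0.11 at the 31.4 percentile, and the 4 mesothelial and pancreatic markers one of -0.18 at the 25.5 percentile, and both medians turned positive under both spike-in scalings, the latter also without a floor. Zap70 was at least 2.03-fold higher and Gzma at least 1.69-fold lower, Cd74 1.44-fold and Itgal 1.08-fold lower. Cpb1 was 1.38-fold and Cela1 1.23-fold lower, Pnlip at least 1.10-fold higher and Ins1 1.04-fold lower.

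**Figure D3:**
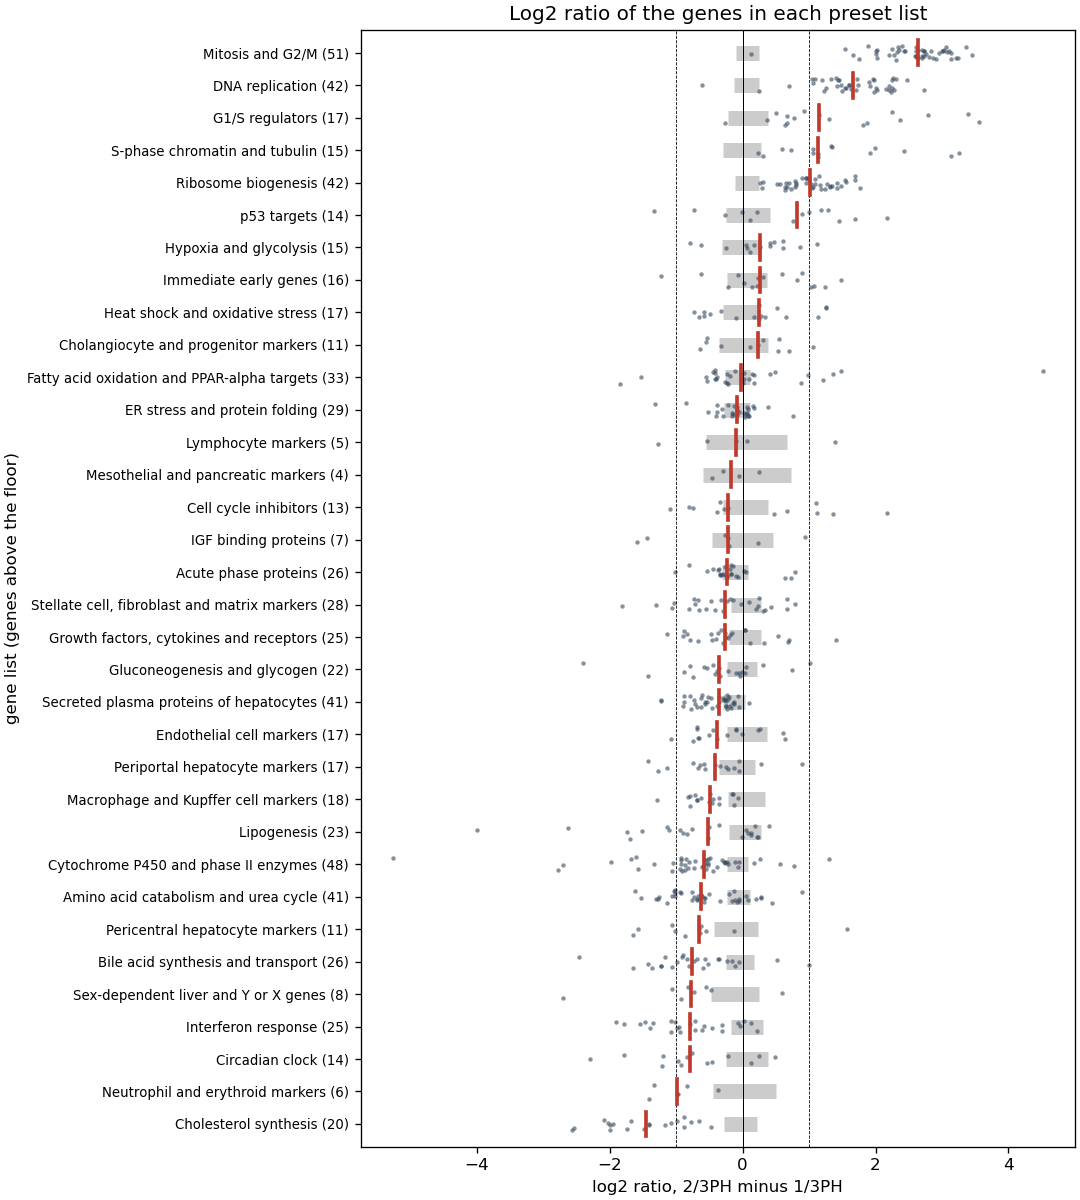
Log2 ratio, 2/3PH minus 1/3PH (x axis), of each gene above the floor (points) in the 34 lists, with the number of genes in parentheses, the list median as a red bar and, in grey, the range of medians of 10000 random lists outside which a list stands apart. Mitosis genes lie furthest right, at a median of 2.63, and cholesterol synthesis genes furthest left, at -1.45, with dashed lines at 2-fold; poly-A scaling moves every point by the same amount to the right and turns 13 medians from negative to positive.

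Between both arrays, 6 of the 34 lists stood apart as higher, 17 as lower and 11 did not. Spiked controls were lower on the 2/3PH array, with a median log2 ratio of -0.24 over 18 hybridisation controls and -0.44 over 24 poly-A controls. Scaling to them, a choice made after the data were seen, moved the median ratio of all genes from 0.03 to 0.27 and 0.48, and the ratios given above are relative to the deposited scaling. The share of 2-fold calls that were higher was 62.4% as deposited, 82.2% with hybridisation controls and 92.9% with poly-A controls, against 56.3% with median centring and 57.2% with quantile normalization. With poly-A scaling the median was -0.15 for drug metabolism, -0.18 for amino acid catabolism, -0.21 for pericentral markers, -0.32 for bile acid genes, -0.33 for the sex-dependent list, -0.35 for interferon, -0.36 for clock and -0.54 for neutrophil and erythroid genes. The 3' to 5' signal ratio was 6.68 and 7.53 for beta-actin and 1.58 and 1.28 for GAPDH, after 1/3PH and 2/3PH. For 2067 genes with several probe sets, the ratios of a pair differed with an SD of 0.44, and 74.3% had the same sign. In 158 of these genes the brightest probe set was at least 2-fold, and the SD was 0.64. The second probe set had the same sign in 148 of the 158 and was at least 2-fold the same way in 94. The spread between probe sets covers measurement within the arrays only, and variation between rats cannot be estimated from pools.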

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

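The scalings to hybridisation and poly-A controls were chosen after the result was seen, and the other alternatives before. No direction was reversed for the lists that stood apart, judged against random lists, but the sign of the list median turned for 13 lists under poly-A scaling, 7 under hybridisation scaling, 2 under loess and 2 without a floor. As higher and lower genes at 2-fold, 582 and 350 were called as deposited. These became 1662 and 1213 without a floor, 285 and 207 with the 75th percentile floor, 973 and 210 with hybridisation control scaling, and 1599 and 123 with poly-A control scaling. At 1.5-fold they were 1504 and 1145, and at 3-fold 213 and 95. The floor and the fold limit change the number of genes by construction, and the scalings shift all ratios alike; whether the controls or the genes differed in amount was not tested. The median of the DNA replication list, 1.66, was 2.10 with poly-A scaling. The median of the mitosis list, 2.63, was 2.78 with the higher floor, 2.29 with 64 units added, 2.87 with hybridisation scaling and 3.08 with poly-A scaling. The SD between probe sets of 1 gene, 0.44, was 1.28 without a floor, where dim signals enter. The lists standing apart numbered 6 to 8 as higher and 15 to 18 as lower over all alternatives. Median centring and both control scalings add the same amount to every ratio. They could therefore not change a list's percentile or its direction against random lists, and only the other alternatives test these. The ratios of the 24 genes with extreme ratios passed 2-fold in each alternative. The exception was 1 of the 12 highest, which had no probe set left without the _s_at, _x_at and _a_at probe sets. These ratios were read whether or not a gene reached the floor, so the 2 alternatives for the floor could not change them. Whether each of the 24 reached the 75th percentile floor was not counted, but some lay under the 75th percentile of either array, 8.76 and 8.86. Among these were Nfe2, Kif18b, Stac3 and Cyp1a1, at mean log2 signals of 6.92, 7.18, 7.59 and 8.35. Leaving out replicates was not possible with 1 array per group. No paired analysis was possible because each group has a single pooled array. Of 156 named genes, 26 fell below 2-fold with poly-A scaling and 8 rose past it. With hybridisation scaling 13 fell below it and 4 rose past it. With 64 units added 18 fell below it, and with the mean over probe sets 4 did. Signal near the floor limits the dim genes, and the number of arrays limits all of them.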

Other observations

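The tests in this part were all chosen after the result was seen, and 8 gene lists were written after the ratios had been looked at. Each reading is therefore a hypothesis, and the percentiles of those 8 lists are not independent evidence. The loess setting and the macrophage, endothelial and stellate lists had been set before the data were examined, but their use as tests of an explanation had not. DNA repair genes were higher, with 17 of 34 at least 2-fold higher and a median log2 ratio of 0.99, above all 10000 random lists. Among members above the floor signal on both arrays, the crosslink repair gene Fancb stood at 2.27 and the exonuclease gene Exo1 at 2.11. Nuclear pore genes were higher too, with 11 of 28 at least 2-fold higher and a median of 0.74, above all 10000 random lists. Nup107 stood at 2.01, Ndc1 at 1.99 and Nup43 at 1.80.

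Of 12 growth hormone responsive genes, 6 were at least 2-fold lower, with a median of -0.80, but the list includes Cyp2c11, Igfbp3 and Igfals, already described as lower. The 9 other members had a median of -0.27 at the 14.4 percentile, so as a list they did not stand apart, and that median turned positive under poly-A scaling. Cish, a feedback inhibitor of cytokine receptors, had signals of 386 after 1/3PH and 96.8 after 2/3PH, Obp3 stood at -1.78, Car3 at -1.31, Igf1 at -0.27 and Ghr at -0.30, and the last pair turned positive under poly-A scaling. Autophagy genes had a median of -0.41, below all 10000 random lists, and positive under poly-A scaling, with 4 of 27 at least 2-fold lower. Ulk2 stood at -1.47, Pink1 at -1.46 and Gabarapl1 at -1.34.

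Higher cell cycle genes after 2/3PH were weighed against 3 explanations. With the loess trend removed the mitosis median was 2.59 against 2.63, so the fitted intensity trend accounted for little of it. That trend was small, since its removal moved the median ratio of all genes from 0.03 to 0.02. The random lists were already matched on signal, so this is not a separate test of an intensity trend. Macrophage, endothelial and stellate lists had medians of at most -0.27 on the deposited scale. With poly-A scaling they were -0.05, 0.06 and 0.18, against 3.08 for the mitosis list. On either scale this argues against a larger share of those cells as the whole source, but a small change in share is not decided. The marker lists do not show which cells divided, and division of those cells at an unchanged share was not tested. A rise in a single rat of the pool stays open, since 1 rat at 16.6-fold with the others at the 1/3PH level would give the same median of 6.20-fold, and no values per rat were analysed here. The extent of resection, which the design names, stays open as an untested biological explanation.

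Lower medians of the clock and lipid synthesis lists may reflect the time of day or feeding. Of the clock genes already described, the Dbp-phase genes had a median of -1.07 at the 0.010 percentile and the Bmal1-phase genes one of 0.18 at the 67.2 percentile, 1.25 apart. A different hour of collection could part them, but only the Dbp-phase genes stood apart from random lists. Of the 4 Bmal1-phase genes above the floor, 3 were higher and 1, Nfil3 at -0.46, was lower. Clock times are not given in the sources used here, so these groups cannot decide the question. A fasting-induced list lay at the 98.8 percentile with Acot1 and at 97.3 without it, short of the limit for standing apart, so passing it rests on Acot1, seen as the highest gene before the list was written; the requirement to pass without Acot1 was added after the full list had passed. Without Acot1, 8 of 11 members were higher and 3 lower, with 0 at least 2-fold higher and 1, Sds, at least 2-fold lower. Food intake and the extent of resection therefore cannot be told apart here.

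Lower Cyp2c11, which is expressed in males, could come from fewer male rats in the 2/3PH pool. The 2 Y-linked genes above the floor had a mean log2 ratio of 0.055, with Eif2s3y at 0.59 and Uty at -0.48, against -2.71 for Cyp2c11. Both lay above that value by more than 0.62, which is 2 SDs of a probe set's ratio. This argues against fewer males as the whole cause of the Cyp2c11 difference, although it rests on 2 genes whose X-linked relatives may share probes. A smaller loss of males would lower the Y-linked genes less and was not tested by this limit. The extent of resection stays open as an untested explanation.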
